A study of Homo sapiens with 10 samples.

How the data were processed

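Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers. The cells were Rh30, an established human alveolar rhabdomyosarcoma line, carrying a PAX3-FOXO1-FKBP fusion. The FKBP part is a degron: the ligand dTAG47 links it to the cell's protein disposal machinery. Per the labels, cells received DMSO, the solvent control, or 500 nM dTAG47 for 2 h, 4 h or 24 h, with 2 H3K27ac libraries per group. The labels give no time for DMSO, and the same DMSO group served the comparisons at every time. Time in culture therefore cannot be told apart from time of treatment. The labels also list 2 input libraries of DMSO-treated cells, which were not analysed here. Per the labels' protocols, sonicated chromatin was precipitated with an anti-H3K27ac antibody and libraries were made with the NEBNext Ultra II kit.

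The deposited table holds raw read counts in 42067 peak windows for the 8 H3K27ac libraries, per the file headers and the values, which are whole numbers with different totals. Of these windows, 42065 differ by 400 between start and end, and the other 2 by 661 and 789. All libraries were counted over one common peak set. Per the submitters' processing notes, the authors used Trimmomatic 0.32, Bowtie2, MACS2, DiffBind and DESeq2 and the builds hg19 (human) and dm3 (Drosophila). The notes give no roles or order. Which libraries the peaks were called in, whether duplicates were removed and whether a spike-in was used is not given in the sources used here. No Drosophila reads were used here. A change common to all peaks therefore cannot be seen in these counts after scaling. Total counts lie within peaks, so neither the sequencing depth nor the enrichment of each library is known from them.

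Columns were matched to groups by name. They carry the letters A and B where the labels carry the numbers 1 and 2, so each library is known by its group only and the tests used no pairing across groups. The number of columns of per-sample values left without a group was 0. Nothing states whether the libraries came from separate cultures, so the spread between them may be technical. P-values measure this spread, taken mostly over all peaks together. The counts of the 2 libraries of each group differed more than sampling noise. The chi-square statistic per degree of freedom was 1.06 for DMSO, 1.21 for 2 h, 1.13 for 4 h and 1.07 for 24 h. In peaks with over 1000 counts in both libraries together it averaged 1.61, 3.65, 2.36 and 1.84. No pair was therefore treated as one library deposited again.

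Coordinates are printed as the deposited table gives them, on hg19. Whether its starts count from 0 or 1 is not stated, so a start may be off by 1 base. The last chromosome 1 peak ends at 249200758. The gene table at hand is on GRCh38, another build, and the deposited table names no genes. Peaks are therefore named by position. The 11 gene lists fixed in advance could not be tested, nor could promoter and distal peaks be separated.

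Counts were tested with edgeR 4.0.16 in R 4.3.3. Peaks passed filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 41791 peaks and left out 276. Library sizes were scaled by TMM. One quasi-likelihood model (robust glmQLFit, glmQLFTest) was fitted to the 4 groups together, because each has 2 libraries. P-values were adjusted by Benjamini-Hochberg and called at 0.05. The common dispersion was 0.00108, a biological coefficient of variation of 3.29%. The spread shared by peaks entered the model with a median of 182 prior degrees of freedom. P-values and standard errors of a peak therefore rest mostly on this shared spread and little on the SD of that peak's own libraries. Levels are CPM scaled by TMM, given as mean ± SD of 2 libraries. Errors of log2 changes are standard errors derived from the F statistic. Peaks within 12.5 kb were also stitched into regions, whose summed counts were tested the same way. Regions were ranked by mean CPM over all 8 libraries, and those above the point where the scaled rank curve has slope 1 are called the strongest.

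For each time against DMSO, the named peaks are the 5 lower and 5 higher with the largest log2 change. They also had to pass the test, have a mean signal at or above the median, and have both treated libraries on one side of both DMSO libraries. The same rule named the regions. The rule, the tests of peaks, regions and overlaps and most alternatives were fixed before the data were examined. Later additions are identified where they are reported.

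The procedure was tested on simulated counts for 41791 peaks with 100 changed peaks per fold. The counts were drawn with the dispersions that edgeR had fitted to these data. The results therefore hold only under that spread, and the simulations cannot test whether it is right. For 2 h against DMSO the procedure recovered 39% of 1.5-fold and 74% of 2-fold changes. For 4 h the shares were 30% and 74%, and for 24 h 41% and 75%. For 4 h against 2 h they were 27% and 71%. Unchanged peaks called in these 4 simulations numbered 9, 5, 6 and 4. Over 26144 simulated regions, 2-fold changes were recovered at 82%, 75% and 76% for 2 h, 4 h and 24 h. Mock comparisons of one library of each group with the other, in all 8 orientations, called between 0 and 32 peaks.

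Alternatives were DESeq2 size factors, total counts and abundance-following offsets as scalings, the DESeq2 1.42.0 Wald test, 2 other filters, fits of the 2 compared groups only, an adjusted p of 0.01, glmTreat against 1.2-fold, stitching within 5 kb or 25 kb, leaving out each library, and the library letter as a block. Set tests used fry and camera of limma 3.58.1 on log2 CPM with a prior count of 2.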

Results

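H3K27ac was measured over 42067 peaks in Rh30 cells in which the PAX3-FOXO1 fusion, the driver transcription factor of alveolar rhabdomyosarcoma, carried an FKBP degron. The 4 groups were DMSO and 2 h, 4 h and 24 h of 500 nM dTAG47, with 2 libraries each. The libraries A and B held 3540104 and 3546020 counts in peaks for DMSO, 3616695 and 4744596 for 2 h, 3641032 and 4044019 for 4 h, and 5001652 and 4369471 for 24 h. The median peak held between 48 and 69 counts per library. The first principal component of log2 CPM, with 28.7% of the variance, ordered the groups by time. DMSO libraries lay at -35 and -35.2, and the 2 h libraries at -8.07 and -7.64. The 4 h libraries lay at 6.77 and 4.27, and the 24 h libraries at 36 and 39. The second component, with 17.5%, did not follow time. On it DMSO (20.6 and 22) and 24 h (19.2 and 18.3) lay together. The 2 h (-19.3 and -19.4) and 4 h libraries (-13.1 and -28.3) lay on the other side. What it reflects was not tested.

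**Figure D1:**
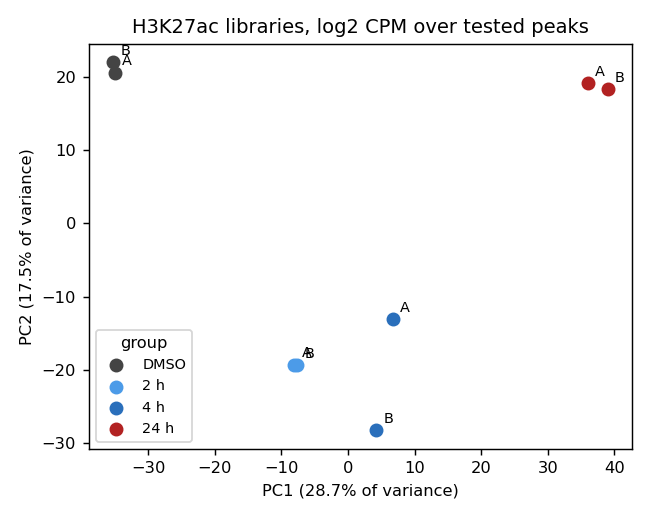
Each point is 1 of the 8 H3K27ac libraries, placed by its first and second principal component of log2 CPM over the tested peaks (percent of variance on the axes); letters are the library letters of the deposited table. The groups run along the first component from DMSO (about -35) to 24 h (36 and 39).

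The comparison of 2 h with DMSO asks which acetylated sites change first once the degrader is added. At 2 h, 431 peaks fell and 81 rose out of 41791 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The median log2 change was -0.79 among the peaks that fell, 0.577 of the DMSO level, and 0.61 among those that rose. A peak on chromosome 1 at 209720421 to 209720821 fell from 27.6 ± 3.6 to 13.3 ± 1.9 CPM (log2 change -1.07, SE 0.18, edgeR adjusted p = 1.18e-05). A peak on chromosome 15 at 59739917 to 59740317 fell from 40 ± 0.7 to 19.4 ± 3.3 CPM. The other named losses were on chromosome 7 at 159004330 to 159004730 (log2 change -1.06) and chromosome 11 at 75067146 to 75067546 (-1.01). A further peak on chromosome 1 at 40427854 to 40428254 fell from 26.7 ± 4.1 to 13.3 ± 0.2 CPM. Among gains, a peak on chromosome 1 at 3446127 to 3446527 rose from 9.2 ± 1.8 to 17.6 ± 2.3 CPM (log2 change 0.94, SE 0.21, edgeR adjusted p = 0.00508). Peaks on chromosome 1 at 32049682 to 32050082, chromosome 15 at 69823910 to 69824310, chromosome 7 at 73424229 to 73424629 and chromosome 2 at 219761616 to 219762016 rose by 0.85, 0.84, 0.80 and 0.77 log2 units. The number of calls rested on both libraries of each arm: 158 fell and 20 rose without DMSO library A, 106 and 13 without B, 253 and 50 without 2 h library A, and 131 and 17 without B. The DESeq2 Wald test called 24 lower peaks, all among the 431, and 0 higher ones; 1969 peaks were higher and 2682 lower at an unadjusted p under 0.05 in edgeR. Of the named peaks, DESeq2 did not call the losses on chromosome 1 at 209720421 (adjusted p = 0.0983) and 40427854 (0.155), chromosome 7 at 159004330 (0.112) or any of the 5 gains (0.578 to 1). Against a 1.2-fold change by edgeR's glmTreat, the 5 gains were not called either (adjusted p from 0.0641 to 0.176). Without DMSO library A, 4 of the 5 gains lost their edgeR call (adjusted p from 0.119 to 0.297), as did the loss at 40427854 (0.0557). Gains that lost it numbered 2 without DMSO library B (0.288 and 0.458), 2 without 2 h library A (0.0925 and 0.225) and 4 without 2 h library B (0.0842 to 0.24).

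At 4 h, 697 peaks fell and 237 rose against DMSO. The median log2 changes of the called peaks were -0.86 and 0.66. The largest named loss was on chromosome 16 at 89608661 to 89609061, from 62.8 ± 4.3 CPM in DMSO to 23.9 ± 1.0 (log2 change -1.39, SE 0.13, edgeR adjusted p = 1.13e-17). Peaks on chromosome 1 at 209699070 to 209699470 and at 209721628 to 209722028 fell by 1.29 and 1.27 on the log2 scale. The peak on chromosome 15 at 59739917 fell by 1.26 and one on chromosome 1 at 59880372 to 59880772 fell by 1.21. The largest named gain was on chromosome 12 at 110157419 to 110157819, from 18.1 ± 2.6 to 36.7 ± 1.4 CPM (log2 change 1.02, SE 0.15, edgeR adjusted p = 3.94e-07). Peaks on chromosome 12 at 49608331 to 49608731, chromosome 19 at 48835540 to 48835940, chromosome 17 at 72228514 to 72228914 and chromosome 19 at 18555225 to 18555625 rose by 0.98, 0.97, 0.93 and 0.92. Lower and higher calls numbered 330 and 69 without DMSO library A, 274 and 58 without B, 382 and 98 without 4 h library A, and 298 and 43 without B. DESeq2 called 78 lower and 4 higher peaks. It called the 5 named losses and, of the 5 named gains, the one at 110157419 (adjusted p of the others from 0.185 to 0.6). In edgeR, the gain at 18555225 lost its call against a 1.2-fold change (adjusted p = 0.108) and without DMSO library A (0.379), 4 h library A (0.0572) or 4 h library B (0.198). The gain at 48835540 lost it without DMSO library A (0.249) or 4 h library B (0.0568), and the gain at 49608331 without DMSO library B (0.0548) or 4 h library B (0.0827).

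At 24 h, 2040 peaks fell and 1448 rose, together 8.35% of those tested. Losses made up 84.2% of the calls at 2 h, 74.6% at 4 h and 58.5% at 24 h. These shares depend on the threshold. At an unadjusted p under 0.05 in edgeR the splits were more even. They were 2682 lower and 1969 higher peaks at 2 h, 2999 and 2459 at 4 h, and 4666 and 4110 at 24 h. With total counts in place of TMM the shares were 83.3%, 68.9% and 52.8%. DESeq2 size factors gave 84.4%, 75.4% and 58.8%, and offsets that follow abundance 83.8%, 75.5% and 58.8%. The scalings hardly differ at 2 h (median log2 change from 0.003 to 0.009), so they cannot show whether scaling shaped the 2 h share. A peak on chromosome 9 at 116984488 to 116984888 fell from 32.3 ± 0.2 to 8.8 ± 0.7 CPM (log2 change -1.87, SE 0.18, edgeR adjusted p = 2.36e-17). The chromosome 16 peak at 89608661 was at 17.4 ± 1.4 CPM (log2 change against DMSO -1.85; against 4 h -0.46, SE 0.16, adjusted p = 0.129). Log2 changes were -1.82, -1.78 and -1.77 for the peaks on chromosome 1 at 3286971 to 3287371, chromosome 15 at 59739917 and chromosome 1 at 209721628. A pair of neighbouring peaks on chromosome 19 rose: the one at 18555225 from 7.1 ± 2.0 to 25.2 ± 3.7 CPM (log2 change 1.81, SE 0.21, edgeR adjusted p = 1.87e-12), and the one at 18554345 to 18554745 from 14.6 ± 1.4 to 35.4 ± 0.5 CPM. Peaks on chromosome 1 at 3446127, chromosome 9 at 92860699 to 92861099 and chromosome 17 at 33474998 to 33475398 rose by 1.30, 1.28 and 1.27. Without DMSO library A 1131 peaks fell and 573 rose, without B 1058 and 594, without 24 h library A 1212 and 666, and without 24 h library B 1194 and 751. DESeq2 called 392 lower and 93 higher peaks, the 10 named ones among them.

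**Figure D2:**
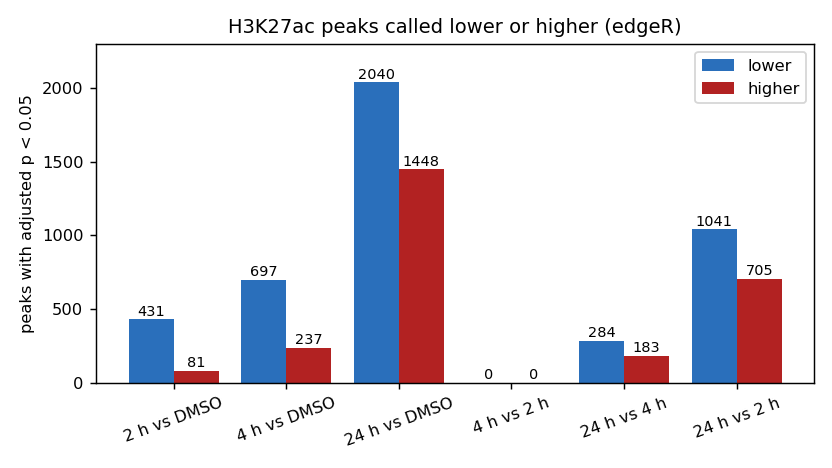
Bars give the number of peaks called lower (blue) or higher (red) in each of the 6 comparisons, at an edgeR adjusted p under 0.05 over 41791 peaks. Calls against DMSO grow from 431 lower and 81 higher at 2 h to 2040 and 1448 at 24 h, and there are 0 for 4 h against 2 h.

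**Figure D3:**
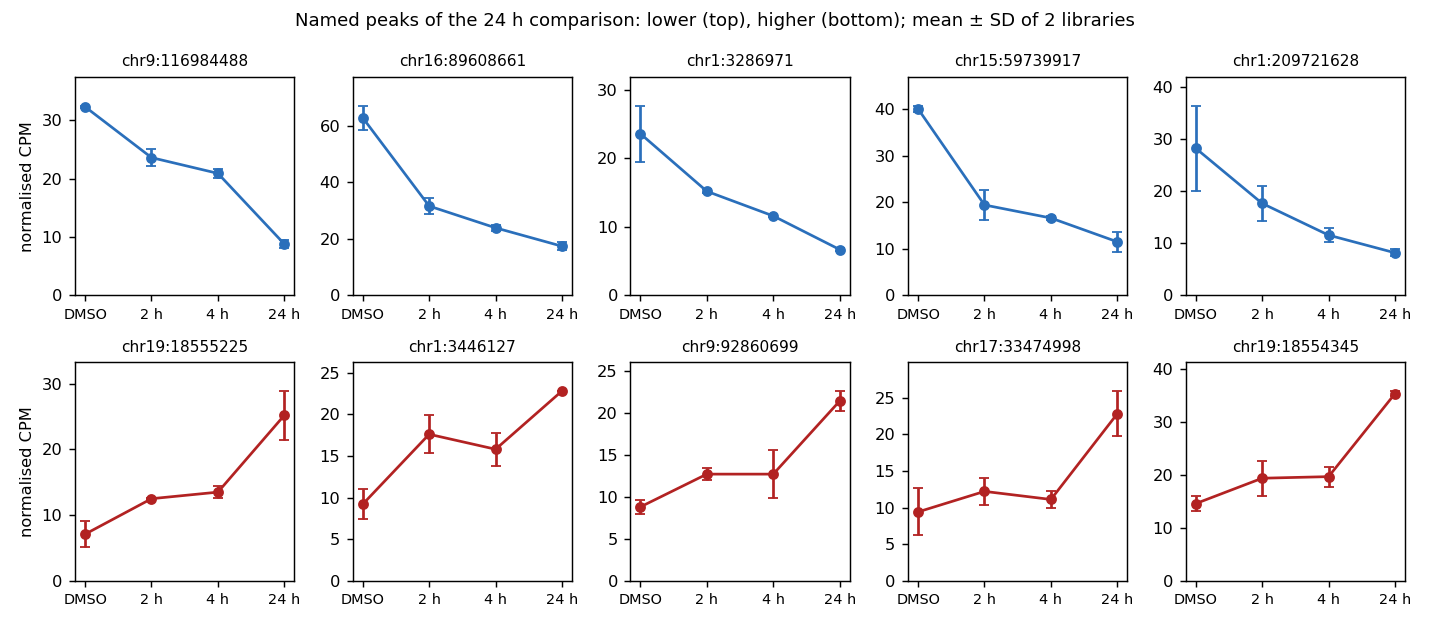
Normalised CPM (vertical axes, from 0) of the 10 named peaks of the 24 h comparison in DMSO and at 2 h, 4 h and 24 h; points are means and bars SDs of 2 libraries, and titles give chromosome and start on hg19. The chromosome 16 peak at 89608661 falls from 62.8 to 17.4 CPM and the chromosome 19 peak at 18555225 rises from 7.1 to 25.2 CPM.

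Comparisons between treated groups asked when the changes occurred. Between 2 h and 4 h, edgeR called 0 lower and 0 higher peaks (DESeq2 also 0), with 1511 lower and 1381 higher at an unadjusted p under 0.05. These 2892 peaks are 6.92% of those tested. In simulated data, 71% of 2-fold and 27% of 1.5-fold changes between these groups were recovered, so most 1.5-fold and some 2-fold changes could be missed at this depth. Above the median abundance the recovered shares were 96% and 57.1%. From 4 h to 24 h, 284 peaks fell and 183 rose, and from 2 h to 24 h, 1041 fell and 705 rose. The chromosome 9 peak at 116984488 fell by 1.25 (SE 0.19) on the log2 scale from 4 h to 24 h (edgeR adjusted p = 6.67e-06). From 2 h to 4 h its log2 change was -0.18 (SE 0.16, adjusted p = 0.872). The chromosome 17 peak at 33474998 rose by 1.02 from 4 h to 24 h. From 4 h to 24 h, lower and higher calls numbered 149 and 109 without 4 h library A, 48 and 34 without B, 74 and 45 without 24 h library A, and 88 and 46 without B; DESeq2 called 3 and 0. From 2 h to 24 h they were 587 and 406 without 2 h library A, 363 and 167 without B, 400 and 180 without 24 h library A, and 435 and 277 without B; DESeq2 called 49 and 12.

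Most early losses were also called later. Of the 431 peaks that fell at 2 h, 315 were also called lower at 4 h and 349 at 24 h, and 0 were called higher at either time. Of the 81 that rose at 2 h, 29 were also called higher at 4 h and 47 at 24 h. Independent lists of these sizes would share 21 lower peaks and 2.81 higher peaks between 2 h and 24 h. These comparisons share the DMSO libraries. In 20 simulations of unchanged groups, lists of calls held at most 4 peaks and shared at most 1, so they do not measure the part of the overlap due to DMSO. Lists of the observed sizes taken from these simulations by lowest p, a test chosen after the overlaps were seen, shared on average 79.8 lower and 15.9 higher peaks for 2 h and 4 h (at most 92 and 22). For 2 h and 24 h they shared 163 lower and 43.2 higher peaks (at most 184 and 54), so the 47 higher peaks shared there lie within the simulated range. The simulations hold no effects and use the dispersions fitted by edgeR. Across peaks, log2 changes at 2 h and 24 h correlated at r = 0.56, against 0.55 in the simulations. For 2 h and 4 h r was 0.66 against 0.53, and for 4 h and 24 h 0.64 against 0.54. Peaks are not independent replicates. The covariance for 2 h and 24 h was 0.0614 against 0.0275 simulated. For 2 h and 4 h it was 0.0615 against 0.0275, and for 4 h and 24 h 0.0762 against 0.0275. With 2 DMSO libraries the controls could not be split into separate sets of 2, so part of the overlap may come from them. The overlap of 2 h and 24 h was 139 lower peaks without DMSO library A and 96 without B, with 10 higher peaks in either case. Without 2 h library A it was 200 lower and 29 higher peaks, and without B 118 and 10. Without 24 h library A or B, 27 and 28 higher peaks were shared. For 2 h and 4 h the lower and higher overlaps were 128 and 10 without DMSO A, 93 and 5 without DMSO B, 189 and 21 without 2 h A, 110 and 8 without 2 h B, 226 and 16 without 4 h A, and 190 and 12 without 4 h B.

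The next comparisons were chosen after the calls were seen. The change from 4 h to 24 h uses neither the DMSO nor the 2 h libraries. Over the 431 peaks that fell at 2 h, its median was -0.08 log2 units, and 269 peaks (62.4%) had a negative value, against 50.2% of all tested peaks. The set as a whole moved down (limma fry p = 0.00947; camera p = 0.0129 with an estimated correlation). The 81 peaks that rose at 2 h had a median of 0.03 (fry p = 0.181; camera p = 0.287 with an estimated correlation). To measure how much of the later change was present early, peaks were chosen with 1 DMSO and 1 24 h library and measured with the others. For 684 lower peaks chosen with the A libraries, the mean log2 change against DMSO was -0.41 at 2 h, -0.55 at 4 h and -0.88 at 24 h. The 2 h change was thus 46.2% of the 24 h change. For 787 peaks chosen with the B libraries it was 47.2%. Higher peaks had reached 30.5% and 33.4% of their 24 h change at 2 h, with 364 and 338 peaks, and 52.1% and 51% at 4 h. Of the 2040 peaks that fell at 24 h, 599 also fell from 2 h to 24 h by the direct test, and of the 1448 that rose, 386 also rose. The 24 h libraries enter both the choice of these peaks and that test, so chance in them inflates both counts.

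Stitching sums the counts of peaks that lie near each other. The peaks formed 26314 regions, of which 18061 were a single peak and 8253 held 2 or more. At 2 h 399 regions fell and 124 rose, at 4 h 523 fell and 254 rose, and at 24 h 1450 fell and 1045 rose, out of 26144 tested. Of these, regions with 2 or more peaks made up 236 and 100 at 2 h, 285 and 193 at 4 h, and 785 and 625 at 24 h. The chromosome 16 region at 89602855 to 89611380, with 3 peaks, went from 113 ± 2.4 CPM in DMSO to 62.9 ± 1.9, 47.1 ± 1.2 and 37.8 ± 2.8 CPM at 2 h, 4 h and 24 h (log2 change at 24 h -1.58, SE 0.09, edgeR adjusted p = 2.37e-44). A region of 2 peaks on chromosome 11 at 19206070 to 19207506 fell by 1.03 on the log2 scale at 2 h, by 1.26 at 4 h and by 1.58 at 24 h. A region on chromosome 5 at 31132974 to 31144704 fell by 1.80 at 24 h, one on chromosome 17 at 37279288 to 37280670 fell by 1.54, and one on chromosome 1 at 209720421 to 209722028 fell by 1.54. Other named losses were on chromosome 1 at 231229320 to 231231002 (-0.92 at 2 h), chromosome 1 at 23134562 to 23135769 (-0.88 at 2 h), chromosome 3 at 58566723 to 58568337 (-0.85 at 2 h) and chromosome 11 at 20297552 to 20298883 (-1.10 at 4 h).

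Among regions that rose, one on chromosome 7 at 127851045 to 127852454 rose by 0.79 at 2 h. One on chromosome 1 at 95338788 to 95340345 rose by 1.17 (SE 0.15) at 24 h, from 17.9 ± 0.0 to 40.4 ± 0.2 CPM (edgeR adjusted p = 5.9e-12). Its log2 change at 2 h was 0.19 (adjusted p = 0.749). Named gains at 2 h were also on chromosome 6 at 37429093 to 37441369 (0.65), chromosome 9 at 98534238 to 98546362 (0.63) and chromosome 15 at 31507794 to 31516569 (0.60). A region of 1 peak on chromosome 17 at 72228514 to 72228914 had a log2 change of 0.67 at 2 h (adjusted p = 0.0417 among regions, 0.0628 among peaks), and its call was lost with offsets that follow abundance (0.0506) and in the fit of 2 groups (0.0525). Named gains at 4 h were on chromosome 17 at 72228514 (0.94), chromosome 11 at 17002810 to 17004112 (0.82), chromosome 14 at 77334000 to 77335452 (0.79), chromosome 11 at 73363032 to 73372294 (0.69) and chromosome 1 at 230961773 to 230963074 (0.67). At 24 h regions on chromosome 1 at 120279589 to 120281009, chromosome 17 at 72228514, chromosome 12 at 90479549 to 90485359 and chromosome 20 at 44767959 to 44768359 (1 peak) rose by 0.98, 0.98, 0.97 and 0.97. Lower and higher regions at 2 h numbered 198 and 60 without DMSO library A, 141 and 37 without B, and 130 and 30 without 2 h library B. At 4 h they were 300 and 100, 250 and 100, 292 and 108, and 257 and 83 without DMSO A, DMSO B, 4 h A and 4 h B, and at 24 h 878 and 512, 821 and 549, 929 and 543, and 872 and 620 without DMSO A, DMSO B, 24 h A and 24 h B. DESeq2 called 38 lower and 4 higher regions at 2 h, 80 and 10 at 4 h, and 355 and 139 at 24 h. Of the regions named at 2 h it did not call those that fell on chromosome 1 at 231229320 (adjusted p = 0.063) and 23134562 (0.0807) and chromosome 3 at 58566723 (0.0835), or the 5 that rose (0.239 to 0.826). Of those named at 4 h it did not call the gains on chromosome 17 at 72228514, chromosome 11 at 17002810 and 73363032 and chromosome 1 at 230961773 (0.0609 to 0.412). Against a 1.2-fold change by glmTreat, none of the 5 gains named at 2 h was called (adjusted p from 0.0656 to 0.414), nor were those named at 4 h at 73363032 (0.164) and 230961773 (0.0684). In edgeR, regions named as gains at 2 h that lost their call numbered 2 without DMSO library A (adjusted p = 0.242 and 0.267), 5 without DMSO library B (0.145 to 0.385), 3 without 2 h library A (0.131 to 0.292) and 3 without 2 h library B (0.0587 to 0.446). The loss at 58566723 was not called without 2 h library B (0.0931). Of the gains named at 4 h, that at 73363032 was not called without DMSO library B (0.169) or 4 h library A (0.264), nor that at 230961773 without 4 h library A (0.0605).

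The 445 strongest regions, with a median width of 30.8 kb and 6 peaks, held 15.3% of the signal. They were called more often than the other 25699 regions. At 24 h 16.9% of them fell and 12.1% rose, against 5.35% and 3.86% of the others (two-sided Fisher's exact test, p = 5.33e-18 and 4.2e-13; regions are not independent replicates). The median log2 change of those that fell was -0.24 in the strongest and -0.62 in the other regions, and of those that rose 0.19 and 0.61. At 2 h 4.27% of the strongest fell and 5.17% rose, against 1.48% and 0.393%. In peaks with over 1000 counts, the chi-square statistic between libraries averaged 3.65 at 2 h and 1.61 in DMSO. The model fits a common spread to all groups, which may understate that at 2 h. Stronger regions hold more counts, so smaller changes pass the test in them. The shares and medians of called regions therefore do not compare how much the classes changed.

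A stretch of chromosome 9 between 133 and 134 Mb, picked after its values were seen, held more peaks that fell at 2 h than any other 1 Mb window outside chromosome Y. Of its 58 tested peaks, 12 fell at 2 h, 11 at 4 h and 18 at 24 h, while 2 rose at 24 h. The peak at 133540074 to 133540474 went from 124 ± 8.82 CPM in DMSO to 73.7 ± 7.07, 59.6 ± 0.108 and 46.1 ± 4.35 CPM at 2 h, 4 h and 24 h. Its log2 change at 24 h was -1.43 (SE 0.09, edgeR adjusted p = 2.59e-31, the smallest of all peaks at 24 h). Its neighbours at 133535360, 133536055 and 133538929 had log2 changes of -1.48, -1.18 and -1.47. Apart from this group, the peak at 133355271 to 133355671 went from 134 ± 1.01 CPM in DMSO to 60.9 ± 9.39 CPM at 24 h (log2 change -1.14). The peak at 133454924 to 133455324, between these positions, had a log2 change of -0.09 at 24 h (adjusted p = 0.604).

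**Figure D4:**
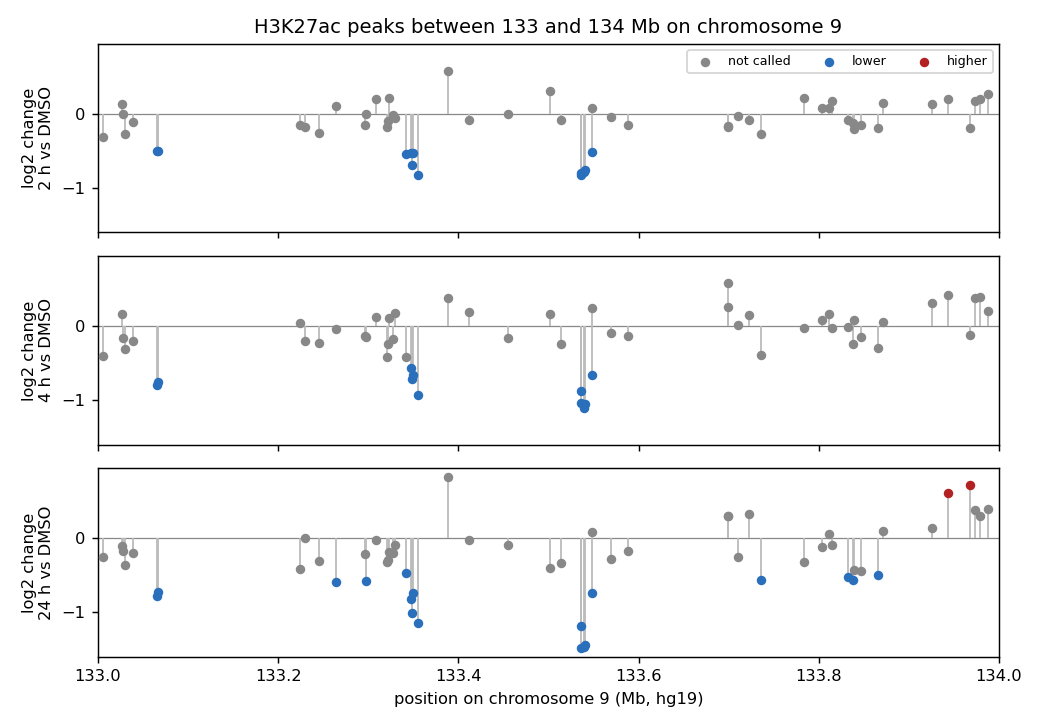
Log2 change against DMSO (vertical axes) at 2 h, 4 h and 24 h of the 58 tested peaks between 133 and 134 Mb on chromosome 9 (horizontal axis, Mb on hg19); blue points are called lower, red higher and grey neither. Lower calls number 12, 11 and 18.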

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

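The tests of neighbouring peaks, shifted 2 h libraries, thinned libraries and weak peaks in this part were chosen after the result was seen; the alternative scalings were planned. Effects at the times differed by the direct test: 1041 peaks were lower and 705 higher at 24 h than at 2 h, and 284 were lower and 183 higher than at 4 h. Leaving out 1 library gave between 363 and 1053 lower and between 167 and 768 higher peaks for 24 h against 2 h, the lowest without 2 h library B. For 24 h against 4 h the ranges were 48 to 307 and 34 to 202, the lowest without 4 h library B.

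Among the named peaks, the log2 change from 2 h to 24 h was -0.72 on chromosome 15 at 59739917, -0.85 on chromosome 16 at 89608661, -1.08 on chromosome 1 at 209721628, -1.43 on chromosome 9 at 116984488 and -1.18 on chromosome 1 at 3286971. It was 1.00 and 0.89 on chromosome 19 at 18555225 and 18554345, 0.76 on chromosome 9 at 92860699 and 0.91 on chromosome 17 at 33474998. Among the named regions it was -0.55 on chromosome 11 at 19206070 and also -0.55 at 20297552, -0.67 on chromosome 1 at 209720421, -0.73 on chromosome 16 at 89602855, -1.01 on chromosome 5 at 31132974 and -0.73 on chromosome 17 at 37279288. It was 0.47, 0.98 and 0.52 on chromosome 1 at 230961773, 95338788 and 120279589, 0.77 on chromosome 12 at 90479549 and 0.96 on chromosome 20 at 44767959. Only named peaks and regions that passed an edgeR adjusted p of 0.05 for 24 h against 2 h are listed here. Of the peaks named as losses at 2 h, only that on chromosome 15 passed. The others were on chromosome 1 at 209720421 (-0.26, adjusted p = 0.545) and 40427854 (0.09, 0.869). The remaining losses were on chromosome 7 at 159004330 (-0.14, 0.784) and chromosome 11 at 75067146 (0.02, 0.976). None of the 5 peaks named as gains at 2 h passed (edgeR adjusted p from 0.215 to 0.98). For those named at 24 h, chance in the 24 h libraries enlarges the value. For those named at 2 h, chance in the 2 h libraries draws the value the other way. A missing call among them therefore does not show that the change was complete at 2 h.

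Losses made up a larger share of the calls at 2 h than later, with 431 lower and 81 higher peaks. At an unadjusted p under 0.05 in edgeR the 2 h split was more even, with 2682 lower and 1969 higher peaks. Scaling between libraries stays open: the share of losses was 84.2% with TMM and at least 83.3% under the 3 other scalings, but these hardly differ at 2 h (median log2 change from 0.003 to 0.009). Shifting the 2 h libraries up moves every peak alike, so a lower share was certain beforehand and only the size of the shift informs. Shifts of 0.03, 0.05 and 0.07 log2 units gave 75.5%, 65.9% and 54.5% (at 0.07, 266 lower and 222 higher). Whether the scaling is off by as much cannot be known from these counts. The libraries in which the peaks were called are not given in the sources used here, so a peak set weighted towards DMSO stays open. The design names degradation of the fusion as a biological explanation. Without treated cells lacking the degron and without DMSO cells for each time, it stays untested.

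Peaks that fell at 24 h lay near each other: 423 pairs of peaks within the stitching distance both fell, where calls permuted among peaks of like abundance gave 59.5 on average and at most 82 in 1000 permutations, a ratio of 7.11. Clustering of strong peaks is therefore argued against as the whole cause. Shared fragments are argued against as the whole cause too, since pairs at least 1 kb apart, too far for most fragments, still had a ratio of 5.61 (267 pairs against 47.6, at most 71 permuted); under 1 kb the ratio was 13.1 (156 against 11.9), so a part from shared fragments stays open. A loss that spreads over wider chromatin stays open: the 1806 peaks at least 1 kb, and at most the stitching distance, from another peak that fell had a median log2 change of -0.17, between the bounds set before the test, with 70.9% below 0 (47.4% of the 18593 other peaks with a neighbour there), 367 called lower and 27 called higher. Peaks that rose at 24 h lay near each other too (280 pairs against 29.5, a ratio of 9.48, and 7.92 at least 1 kb apart), and the 1550 peaks at such a distance from another peak that rose had a median of 0.19, so neither is particular to losses.

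The weakest 8359 peaks had a median log2 change of 0.084 at 24 h, the strongest 8358 peaks -0.03. A bias that comes with the greater total counts in peaks of the 24 h than the DMSO libraries stays open. Thinning them to the smallest DMSO total keeps the expected share of each peak. The median of 0.085 after it therefore cannot decide (-0.004 in counts simulated with unchanged shares). Higher calls there went from 249 to 190. For single libraries, the medians given here are of log2 CPM minus its mean over all 8 libraries, not changes against DMSO. Such medians followed the totals in part. The largest total, in 24 h library A (5001652), had a median of 0.122. However, 2 h library B held more counts (4744596) than 24 h library B (4369471), with medians of -0.082 and 0.068. Whether a trend with abundance raised the number of gains called there stays open. With offsets that follow abundance, 192 of the 249 higher peaks among the weakest kept their call, while lower calls there went from 256 to 343. The smallest log2 change called there was 0.82. Removing a shift near 0.084 could therefore hardly take away most of these calls, and the number kept cannot decide. For the median shift itself, drift between libraries stays open, by a test set after its values were seen: the medians of single libraries differed by 0.125 between the 4 h libraries and were 0.029 and -0.082 at 2 h. They were 0.016 and 0.021 in DMSO and 0.122 and 0.068 at 24 h, so both 24 h libraries lay above both DMSO libraries.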

How the results depend on the processing

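The planned fits with the replicate number as a block were not run because the columns carry letters, and nothing states what a letter shares across groups. With the letter as a block, an alternative chosen after seeing the data, 449 peaks fell and 88 rose at 2 h, 711 and 249 at 4 h, and 2087 and 1478 at 24 h. Differences between libraries A and B correlated between groups at r from -0.033 to 0.054 across peaks, which are not independent replicates. The gene list and promoter alternatives were not run for lack of an hg19 annotation. For overlaps, alternatives other than the stricter threshold, and for regions those other than DESeq2 size factors, stitching distances and left-out libraries, were chosen after seeing the data. Under the 3 other scalings, without a filter, with 2-group fits, with the letter block and with stitching within 5 kb or 25 kb, every count of peaks, overlaps and regions stayed within 1.5 times. No named peak or region changed direction under any alternative run. The naming rule largely fixed this, since it puts both treated libraries on the same side of both DMSO libraries. Leaving out a library or moving a threshold could then hardly reverse a direction. Calls were lost in 4 of 270 values of lower named peaks and 37 of 270 of higher ones. For regions they were lost in 4 of 270 values of lower and 36 of 270 of higher ones.

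The DESeq2 Wald test called far fewer peaks: 24 lower and 0 higher at 2 h, 78 and 4 at 4 h, 392 and 93 at 24 h, 3 and 0 for 24 h against 4 h, and 49 and 12 for 24 h against 2 h. Overlaps were 21 lower and 0 higher for 2 h and 4 h, and 23 and 0 for 2 h and 24 h; regions were 38 and 4, 80 and 10, and 355 and 139 at 2 h, 4 h and 24 h. Its fitted variance at the median peak was 2.43 times Poisson, edgeR's 1.09 times, and that between the libraries of a group 1.06 to 1.21 times over all peaks and 1.61 to 3.65 times in peaks with over 1000 counts, so the gap in calls goes with DESeq2's larger dispersion. At an adjusted p of 0.01, calls were 182 and 19, 368 and 56, and 1199 and 664 at 2 h, 4 h and 24 h, 122 and 52 for 24 h against 4 h, and 418 and 220 for 24 h against 2 h; overlaps were 144 and 7, then 159 and 13; regions were 189 and 39, 302 and 98, and 887 and 540. Against a 1.2-fold change, glmTreat called 97 and 0, 251 and 18, and 926 and 472 peaks at the 3 times, 14 and 11 for 24 h against 4 h, and 187 and 122 for 24 h against 2 h; overlaps were 79 and 0, then 89 and 0; regions were 69 and 0, 139 and 9, and 510 and 253. Among peaks at or above the median abundance, where fewer peaks were tested, 432 peaks fell at 4 h, 1133 fell and 962 rose at 24 h, 224 lower peaks were shared by 2 h and 24 h, and 833 regions fell at 24 h.

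Leaving out 1 library, where the lone library of its group is assumed to vary like the others, gave 106 to 463 lower and 13 to 86 higher peaks at 2 h, 274 to 721 and 43 to 255 at 4 h, and 1058 to 2120 and 573 to 1531 at 24 h. For 4 h against 2 h it gave 0 to 1 higher peaks (1 without 2 h library A), for 24 h against 4 h 48 to 307 lower and 34 to 202 higher, and for 24 h against 2 h 363 to 1053 and 167 to 768. Overlaps were 93 to 310 lower and 5 to 27 higher for 2 h and 4 h, and 96 to 368 and 10 to 52 for 2 h and 24 h. Regions were 130 to 391 and 30 to 118 at 2 h, 250 to 523 and 83 to 256 at 4 h, and 821 to 1473 and 512 to 1057 at 24 h. The low ends came from removing a library of an arm compared, which leaves fewer samples. Depth limits the weak peaks most: the smallest log2 change called at 24 h was 0.82 among the weakest 8359 peaks and 0.17 among the strongest 8358.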

Other observations

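All values in this part were chosen after they were seen. On chromosome 16, the peak at 1480950 to 1481350 went from 75.8 ± 4.73 to 27.2 ± 1.09 CPM at 24 h. On chromosome 20, the peak at 61155329 to 61155729 rose at every time, from 58.3 ± 0.888 to 84 ± 0.0929, 92 ± 0.239 and 121 ± 2.37 CPM, and its neighbour at 61164142 to 61164542 from 41.4 ± 2.15 to 85.2 ± 0.832 CPM at 24 h.

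Gains at 24 h were frequent in a few windows. On chromosome 14 between 105 and 106 Mb, 17 of 90 peaks rose and 0 fell, and on chromosome 17 between 17 and 18 Mb, 16 of 78 rose and 0 fell. On chromosome 2 between 241 and 242 Mb, 15 of 63 rose and 5 fell, on chromosome 9 between 92 and 93 Mb, 12 of 40 rose and 1 fell, and on chromosome 21 between 46 and 47 Mb, 11 of 74 rose and 2 fell. Losses at 24 h were frequent, among others, on chromosome 9 between 89 and 90 Mb (14 of 68 peaks fell and 1 rose) and on chromosome 17 between 27 and 28 Mb (12 of 58 fell and 3 rose). On chromosome 1 they were frequent between 59 and 60 Mb (13 of 64), 20 and 21 Mb (12 of 29) and 8 and 9 Mb (12 of 41), and 0 rose in these 3. The share of stitched regions that rose at 24 h was 6.58% on chromosome 20 and 5.89% on chromosome 9, against 4% over all chromosomes (Fisher's exact test, adjusted p = 0.0043 and 0.0049 over 23 chromosomes; regions are not independent replicates). It was 1.38% on chromosome X (adjusted p = 0.0035). Regions that fell made up 3.75% on chromosome 3 against 5.55% over all chromosomes (Fisher's exact test, adjusted p = 0.0245). Calls depend on the counts a region holds, and these tests made no allowance for that. The shares therefore do not compare how much the regions of each chromosome changed. By the direct test from 2 h to 24 h, 48 of the 431 peaks that fell at 2 h fell further and 18 moved back up, while 3 of the 81 that rose rose further and 10 moved back down. The 2 h libraries enter both the choice of these peaks and this test, so chance in them inflates the counts of peaks that moved back. One of these 10, on chromosome 9 at 130678593 to 130678993, went from 38.1 ± 3.16 CPM to 57.4 ± 0.951 at 2 h and 43.1 ± 4.03 at 24 h. The densest 1 Mb window was on chromosome 12 between 58 and 59 Mb, with 125 peaks against a median of 11 over 2646 windows; 3 of its peaks fell and 5 rose at 24 h.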
